A study of Mus musculus with 2 samples.

How the data were processed

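Total RNA was measured in adrenal glands of 2-month-old male B6CASTF1/J mice, the F1 hybrid of the strains C57BL/6J and CAST. The series holds 2 libraries in 1 group, labelled biological replicates 1 and 2, each made from 300 ng of RNA with a directional (stranded) library kit after ribosomal RNA reduction, with ERCC spike-ins (synthetic RNAs of fixed mixture) added, per the labels. The sample descriptions give the replicates different animal numbers, while the library descriptions give both the same number and the donor field gives both the same identifier. That the libraries come from 2 animals therefore rests on the sample descriptions. With 1 group there was no comparison between conditions, and replicate 2 against replicate 1 compares 1 library with 1 library.

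Per the labels and the deposited file notes, the genome build was mm10 (GRCm38) and the annotation GENCODE M21. Whether reads from CAST alleles were assigned as well as reads from the other parent strain was not tested. Names and versions of the aligner and quantifiers were not given in the sources used here. For each library the authors deposited a gene table and a transcript table that derive from alignments to the transcriptome, called alignment-based below, whose column names are those RSEM writes. They also deposited a transcript table that derives from 2 read files and an index, called read-based, whose column names are those kallisto writes. The deposited alignment-based tables give expected counts (reads shared among transcripts by the quantifier, so not whole numbers), TPM and FPKM, per the file headers. The deposited read-based tables give estimated counts and TPM, per the file headers. The authors' alignment-based transcript tables also hold the percent of a gene's transcripts assigned to each isoform, which was not used; isoform shares were computed from TPM. Signal tracks listed in the file notes were not analysed here.

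The effective lengths the authors deposited differ between the tables. The alignment-based effective length was the transcript length minus 99 bases for 100% of the transcripts over 300 bases. The read-based effective length of long transcripts was the length minus 325 bases in replicate 1 and 326 bases in replicate 2 (medians). TPM divides by the effective length, so the quantifiers scale short transcripts differently. The 28639 transcripts under 100 bases held 0 expected counts.

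The gene table lists 55536 genes, 96 ERCC rows and 26248 transfer RNA rows, which held 4.66 and 4.42 counts. All 55536 gene identifiers were in the M21 annotation, and 55450 had a symbol in the gene name table. Read-based values were summed per gene. Expected and estimated counts were rounded to whole numbers for count models. The replicate dispersion was edgeR's common dispersion with an intercept alone and TMM scaling, over genes with 10 or more counts in both libraries. DESeq2 served as an alternative. Ratios are log2 of replicate 2 over replicate 1, from expected counts plus 0.5 divided by the TMM-scaled library sizes. Each gene's 95% interval is the exact Clopper-Pearson interval of the share of its counts in replicate 2, and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were called over 2-fold apart at a mean of 100 or more counts.

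Before the data were examined, 31 gene lists were fixed for the cortex and its zones, the medulla, other cell types of the gland, blood, fat and neighbouring organs, stress, clock and division programs, the mitochondrion, and control genes. A list's median ratio over members with a mean of 20 or more counts was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list with fewer than 4 such members got no percentile. A percentile under 2.5 or over 97.5 is described as standing apart. Random lists ignore that genes of 1 cell type vary together, so percentiles describe these libraries and are not tests. The named genes are the 4 members of each list with the highest mean TPM, any member of the steroidogenesis and chromaffin lists, the 15 nuclear protein-coding and 5 other genes of highest mean TPM, the 10 genes each way with the largest ratio, and the 5 genes each way with the largest difference between quantifiers at a TPM of 10 or more. Other named genes are said to have been chosen after their values were seen. Values of some single genes that the rule would name are not reported here.

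The procedures were tested on simulated data drawn from the real means and library sizes. For the dispersion, a simulated value of 0.01 was recovered as 0.00989 over 16859 genes with no gene changed, and as 0.0147 over 16863 genes when 200 genes were changed by 1.5-fold or 3-fold, so changed genes raise the estimate. For the number of genes over 2-fold, 97% of the 3-fold changes and 4% of the 1.5-fold changes were called among 12430 genes, with 1 of 12230 unchanged genes. For the list ratio, 2.5% of 200 unchanged lists of 12 genes stood apart and 96% of the lists shifted by 0.3 (log2) were placed above, from a pool of 15651 genes. Simulated genes varied independently and the lists were random, so these rates do not hold for lists whose genes vary together. Alternatives changed the detection threshold, the unit, the pseudocount, the scaling, the count filter, the quantifier and the replicates used. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.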

Results

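Total RNA-seq was carried out on adrenal glands of male F1 hybrid mice at 2 months of age, with 2 libraries in 1 group. The gene tables held 36512736 expected counts in replicate 1 and 34454892 in replicate 2, and the read-based tables held 35315387 and 33397838 estimated counts. Nuclear protein-coding genes took 62.3% of the expected counts in replicate 1 and 65.2% in replicate 2. Mitochondrial ribosomal RNAs took 13.8% and 11.1%, mitochondrial mRNAs 5.78% and 4.5%, small noncoding RNAs 9% and 9.5%, and long noncoding genes 5.26% and 6.36%. Small noncoding RNAs are short, so they held 447168 and 476346 TPM of a total of 1000000. A TPM of 1 or more in both libraries was reached by 13001 genes, of which 11944 were protein-coding. A further 250 genes reached it in replicate 1 alone and 407 in replicate 2 alone. A TPM of 100 or more in both libraries was reached by 449 protein-coding genes.

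The most abundant nuclear mRNA was that of Star, which moves cholesterol into mitochondria, at 5617 ± 456 TPM (SD, n = 2). Star (ENSMUSG00000031574.8) lies on chromosome 8 from 25806555 to 25815982 in GRCm38. Among the enzymes of corticosteroid synthesis, Hsd3b1 stood at 3617 ± 47.3 TPM, Cyp11a1, which cleaves the cholesterol side chain, at 2223 ± 106 TPM and Cyp21a1 at 1828 ± 287 TPM. Cyp11b1, the enzyme of the final step to corticosterone, stood at 1457 ± 192 TPM and Cyp11b2, the aldosterone synthase, at 198 ± 27.8 TPM. The electron carriers Fdx1 and Fdxr stood at 727 ± 84.8 and 453 ± 36.9 TPM, the lipoprotein receptor Scarb1 at 734 ± 40.8 TPM and the ACTH receptor Mc2r at 99.4 ± 0.382 TPM. Cyp17a1, the 17-hydroxylase needed for cortisol, had 58 and 53 counts and 0.86 ± 0.0141 TPM. Hsd11b2 had 3 and 7 counts. The steroidogenesis list summed to 1.9 ± 0.131% of TPM, and 17 of its 19 members reached 1 TPM in both libraries. With read-based TPM the list held 3.65%. Hsd3b1 and Hsd3b6, and Cyp11b1 and Cyp11b2, are close copies that can share reads, so their separate values are uncertain. Cyp21a1, and Akr1b7 and Agtr1a below, were also fixed in the list of genes with close copies, so the same caution holds.

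Markers of the outer cortical zone, the glomerulosa, were led after Cyp11b2 by Dab2 at 107 ± 4.96 TPM and the angiotensin receptor Agtr1a at 74.7 ± 0.87 TPM. Markers of the inner zone, the fasciculata, included Akr1b7 at 1764 ± 4.23 TPM, Srd5a2 at 1077 ± 191 TPM and the transporter Abcb1b at 853 ± 137 TPM. In the list for the X-zone, an innermost layer of the mouse cortex, Akr1c18 had 6 and 4 counts, while Thrsp, which fat cells also express, stood at 156 ± 6.17 TPM.

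The chromaffin list, for the cells of the medulla that make catecholamines, summed to 0.288 ± 0.0272% of TPM, and all 20 members reached 1 TPM in both libraries. With read-based TPM it held 0.565%. The granule proteins Chgb and Chga stood at 685 ± 59 and 594 ± 47.8 TPM, and the neuropeptide Npy at 404 ± 55.9 TPM. Of the catecholamine enzymes, Th stood at 364 ± 43.5 TPM, Dbh at 172 ± 16.8 TPM, Pnmt, which makes adrenaline, at 164 ± 13.5 TPM and Ddc at 25.8 ± 1.1 TPM. Chgb (ENSMUSG00000027350.8) lies on chromosome 2 from 132781278 to 132795079.

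**Figure D1:**
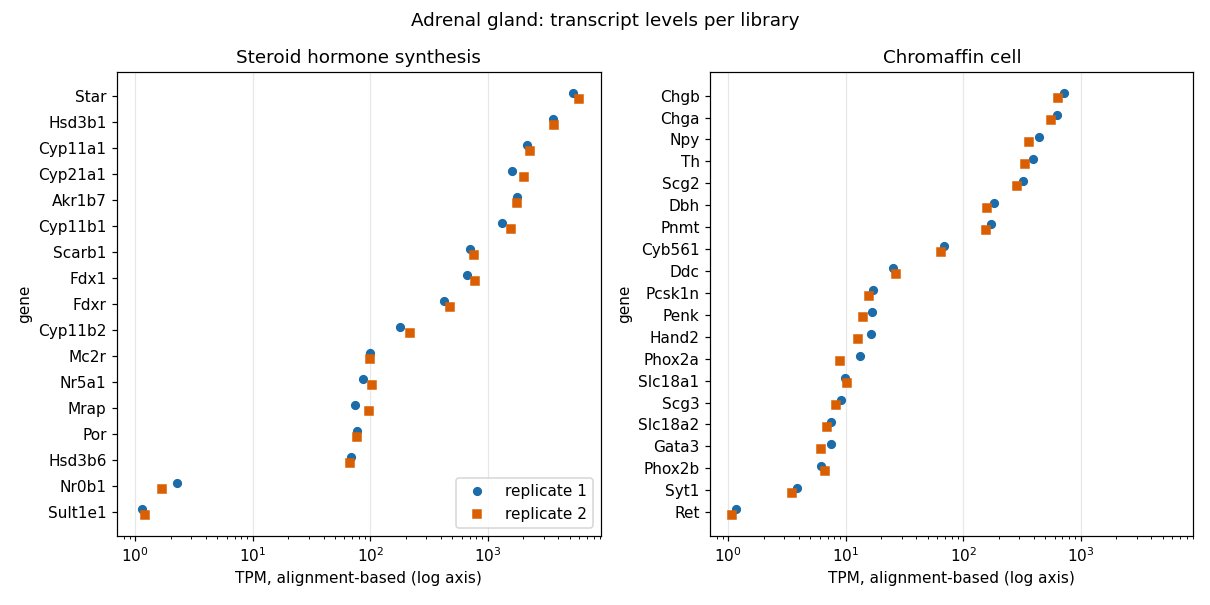
TPM of the members of the steroidogenesis list (left) and the chromaffin list (right) with a mean of 1 TPM or more, on a log axis; circles are replicate 1 and squares replicate 2, each a single library. Star leads the left panel at 5294 and 5939 TPM, and Chgb leads the right panel at 727 and 643 TPM.

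Transcripts of fat and blood were also present. The white adipocyte list held 0.352 ± 0.0595% of TPM, with the fatty acid binding protein Fabp4 at 1279 ± 299 TPM and the protease Cfd at 1207 ± 95.6 TPM. The brown adipocyte list held 0.155 ± 0.0531%, with the uncoupling protein Ucp1 at 466 ± 230.3 TPM, and the red cell list 0.156 ± 0.0547%. The endothelial list held 0.0331 ± 0.00247% and the smooth muscle list 0.0137 ± 0.0017%. The potassium channel Kcnk3, fixed as a brown adipocyte marker, stood at 378 ± 10.1 TPM, within a list total of 1927.8 and 1176.5 TPM in replicates 1 and 2. Its log2 ratio between the libraries was -0.02, where the list's median was -0.93. The brown adipocyte share is therefore too high for brown fat if other cells express Kcnk3, which was not tested. Among endothelial markers Plvap stood at 67.9 ± 6.48 TPM, among stromal markers the proteoglycan Dcn at 87.5 ± 10.6 TPM, among smooth muscle markers Tagln at 72.4 ± 7.33 TPM, and among macrophage markers Lyz2 at 48.9 ± 0.233 TPM. Markers of neighbouring organs were scarce, since the kidney list held 0.000471 ± 0.000238% of TPM and the liver list 0.00068 ± 0.000411%. By library these were 0.000303% and 0.00064% for kidney and 0.00039% and 0.000971% for liver, in replicates 1 and 2. The pancreas list held 0.00264 ± 8.84e-05%, nearly all from Cela1 at 25.8 ± 1.1 TPM, and the lymphocyte list held 0.00159 ± 2.76e-05%, mostly from Ighm at 13.1 ± 0.608 TPM. These lists and the X-zone list had 3, 0, 2, 1 and 1 members, in that order, below 0.1 TPM in both libraries. The Y-linked Ddx3y stood at 25.2 ± 1.2 TPM and Xist, named after its value was seen, at 0.01 TPM in each library. Outside the nuclear mRNAs, the signal recognition particle RNAs Rn7s1 and Rn7s2 were highest at 178491 ± 9077 TPM each. Their sequences are identical and the counts are split evenly, so neither value can be assigned to its locus. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 50634 ± 8595 and 49726 ± 5437 TPM and Rn7sk at 38951 ± 1495 TPM.

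Replicate 2 was compared with replicate 1 to measure the spread between the libraries. Across 13658 genes with 1 TPM or more in either library, Pearson's r of log2(TPM + 1) was 0.9863 and Spearman's rho 0.9861, where genes are not independent replicates. The common dispersion was 0.0105 over 16789 genes, a biological coefficient of variation of 0.103. A chi-square statistic of 35.7 per gene showed that the libraries differed beyond sampling noise, so they were not treated as a single library deposited again. It does not show that they come from 2 animals. Of 12430 genes with a mean of 100 or more counts, 97.3% lay within 1.5-fold and 56 lay over 2-fold apart, 28 higher and 28 lower in replicate 2. Scaling by total count gave 38 higher and 19 lower, and the ratio of TPM gave 48 higher and 23 lower. The median log2 ratio of the 12430 genes was -0.004 with TMM, 0.069 with total count and 0.084 with the TPM ratio. Part of the change under the TPM ratio, here and in list medians below, is therefore a shift shared by most genes. With 1 library on each side the differences between the replicates have no replicate check.

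Lists of fat, blood, mitochondrial, medullary and stromal genes had median ratios below 0 for replicate 2 over replicate 1. The brown adipocyte list had a median log2 ratio of -0.93, with 8 of 8 members lower. Ucp1 (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452) had 629 TPM in replicate 1 and 303 TPM in replicate 2, a log2 ratio of -1.15 (95% counting interval -1.17 to -1.12). Cox8b had a log2 ratio of -1.0 and Cidea of -1.1, while Kcnk3 stood at -0.02. The white adipocyte list had a median of -0.51 with 8 of 8 lower, among them Fabp4 at -0.57 and Cfd at -0.26. The red cell list had a median of -0.76 with 5 of 5 lower, including the globins Hba-a1 at -0.85 and Hbb-bs at -0.76, whose close copies make the separate values uncertain. Mitochondrially encoded mRNAs had a median of -0.44 with 13 of 13 lower, and mt-Co1 was at -0.36. Nuclear genes of the respiratory chain had a median of -0.43 with 15 of 15 lower, including Atp5b at -0.38 and Cox4i1 at -0.42. These respiratory lists were lower in the same library as the brown adipocyte list.

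The chromaffin list had a median of -0.26 (-0.17 with the TPM ratio), with 20 of 20 members lower and 16 beyond counting error, such as Th at -0.34, Npy at -0.38 and Phox2a at -0.63. The list's percentile was 0 with either ratio. The capsule and stroma list had a median of -0.33 with 10 of 11 lower, 9 beyond counting error, including Col3a1 at -0.53. The smooth muscle list had a median of -0.36 with 8 of 8 lower. The imprinted gene list had a median of -0.22 with 10 of 12 lower, 8 beyond counting error, including Dlk1 at -0.24. The Schwann and glial list had a median of -0.29 with 7 of 8 lower, of which 3 lay beyond counting error. At a minimum of 100 counts its median of -0.18 no longer stood apart, at percentile 4.92. All of these medians lay below the central 95% of matched random lists, and the fat, blood, chromaffin and stromal lists were lower in the same library.

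Lists of cholesterol supply, stress hormone response, interferon response and cell division had median ratios above 0. The cholesterol supply list had a median log2 ratio of 0.23 with 17 of 19 members higher, 16 beyond counting error, and a median of 0.35 with the TPM ratio. The list's percentile was 100 with either ratio. Dhcr7, of the last step of cholesterol synthesis, was at 0.25 and Msmo1 at 0.44, while the lipase Lipe, also a fat cell enzyme, was at -0.49. The glucocorticoid response list had a median of 0.23 with 7 of 10 higher, 6 beyond counting error, where Per1 was at 1.12 and the metallothionein Mt1 at -0.07. The interferon list had a median of 0.38 with 10 of 12 higher, 5 beyond counting error, including Mx2 at 0.73. The division list had a median of 0.57 with 10 of 11 higher, of which 5 lay beyond counting error. Its levels were low, with Cdk1 at 1.61 ± 0.552 TPM. The heat shock list had a median of 0.16 (0.3 with the TPM ratio) with 8 of 11 higher, with Hspa8 at 0.13, Hsp90aa1 at -0.35 and Hspb1 at -0.6. The nuclear noncoding RNA list had a median of 0.14 with 7 of 10 higher, and 0.27 from read-based counts, and Malat1 was at 0.56. The read-based median is not over the same members, since Rmrp and Rn7sk had too few read-based counts to be compared. All of these medians lay above the central 95% of matched random lists.

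The liver list, which also lay above it, had the largest median of the 28 lists, 2.01, with 6 of 6 members higher and 5 beyond counting error, at low levels. Albumin, Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), had 66 and 347 counts, 0.88 and 5.06 TPM. The kidney list had a median of 0.74 from 4 members, led by Kap with 30 and 90 counts, but with the TPM ratio its median of 0.43 lay at percentile 91.88, and at a minimum mean of 5 counts it was 1.22. Of the 28 lists with a percentile, 10 lay below and 8 above the central 95%, where 1.4 would by chance if genes varied independently.

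**Figure D2:**
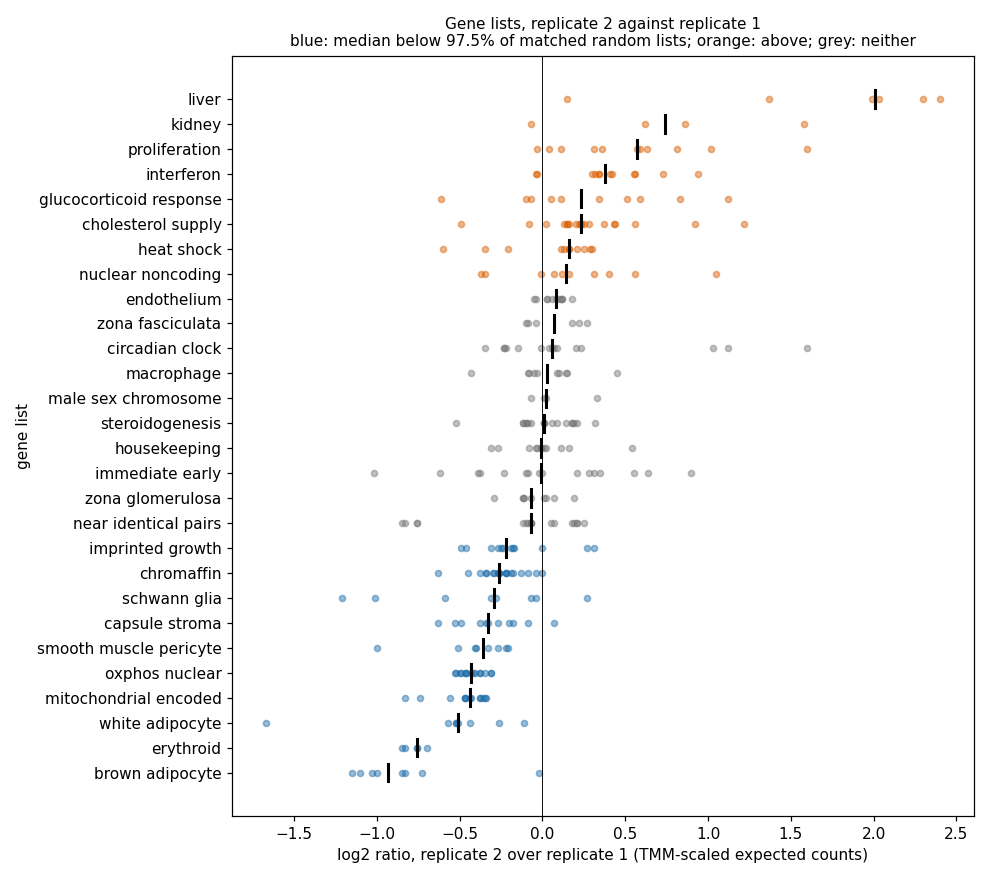
Log2 ratio of replicate 2 over replicate 1 from TMM-scaled expected counts, for each gene list (rows) with each member as a point and the median as a black bar; colours mark medians below (blue), above (orange) or within (grey) the central 95% of matched random lists. The brown adipocyte list lies lowest at -0.93 and the liver list highest at 2.01, while steroidogenesis lies at 0.01.

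The steroidogenesis list did not stand apart, with a median of 0.01 at percentile 65.51. Star was at 0.09, Cyp11a1 at 0.01, Cyp21a1 at 0.21 and Nr0b1, a nuclear receptor with 150 and 104 counts, at -0.52. The glomerulosa list had a median of -0.07, the fasciculata list 0.07, endothelium 0.08, macrophages 0.03, common reference genes -0.01, the Y-linked and Xist list 0.02 and the genes with close copies -0.07. The immediate early list had a median of -0.01 with members in both directions, Nr4a1 at 0.9 and Egr1, chosen after its value was seen, at -0.62. At a minimum of 100 counts its median was 0.1, at percentile 98.06. The clock list had a median of 0.06.

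Single genes with the largest ratios included several of the tissue markers above. Lower in replicate 2 were the fat hormone Lep at -1.67 (95% counting interval -1.99 to -1.36), Fabp3 at -1.58, Dhrs9 at -1.45, Gmpr at -1.41, Slc25a34 at -1.36, Lgr6 at -1.33, Gm10032 at -1.23, Bcl6 at -1.22 and S100b at -1.21. S100b was fixed in the Schwann and glial list, but its cell of origin is not shown here. Gm44502 had 274.5 counts in replicate 1 and 0 in replicate 2, but 1639 and 1109 estimated counts in the read-based tables, and is reported as uncertain. Higher in replicate 2 were Alb at 2.4, Susd3 at 2.3, the interferon-induced GTPase Tgtp2 at 2.14, Alox15 at 2.01, Gm12185 at 1.64, Mup7 at 1.49, Plk3 at 1.45, Prg4 at 1.44, H2-Q1 at 1.38 and Hhex at 1.36. Tgtp2, Mup7 and H2-Q1 belong to families of close copies and are uncertain, and H2-Q1 was at 0.61 from read-based counts.

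The same libraries quantified by the other method gave different TPM. Of 15863 genes with 1 TPM or more by either method, 4938 differed by more than 2-fold in the same direction in both libraries, 4439 higher and 499 lower in the read-based table. The median log2 ratio of read-based over alignment-based TPM was 0.86 in replicate 1 and 0.94 in replicate 2, and after centring on these medians 1290 genes differed, 710 higher and 580 lower. TPM sums to 1000000 in each table, so short RNAs nearly absent from the read-based tables raise the TPM of all other genes there. Rn7s1 and Rn7s2, at a mean of 178491 TPM each by alignment, had 1.68 and 1.91 read-based TPM each in replicates 1 and 2. Much of the uncentred difference is therefore a shared rescaling. Pearson's r of log2(TPM + 1) across genes was 0.854 in replicate 1 and 0.848 in replicate 2, and Spearman's rho 0.893 and 0.891. Among 13363 protein-coding genes r was 0.975 and 0.972 and rho 0.978 and 0.977, with 3421 genes more than 2-fold higher and 46 lower in the read-based table. The mitochondrial gene mt-Atp8, annotated at 204 bases, had 21732 and 16549 expected counts but 0 estimated counts. The RNA Rmrp, of 271 bases, had 28401 and 29618 against 0, and the small nuclear RNA genes Gm23444, Gm23472 and Rnu2-10, of 191 bases, were also at 0. Conversely the pseudogene Gm28439 had 0 expected counts but 6512 and 5133 estimated counts, and Gm22567, Gm47283, Gm45837 and Gm10709 were likewise at 0 in the alignment-based tables.

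Among genes with 1 transcript and 200 or more counts in replicate 1, the median ratio of read-based to alignment-based counts was 0 for 75 genes under 325 bases, 0.299 for 47 genes of 400 to 500 bases and 1.09 for 549 genes of 2000 bases or more. For ERCC spike-ins it was 0.542 for 7 spike-ins of 500 to 700 bases and 0.811 for 14 of 1000 to 2000 bases.

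**Figure D3:**
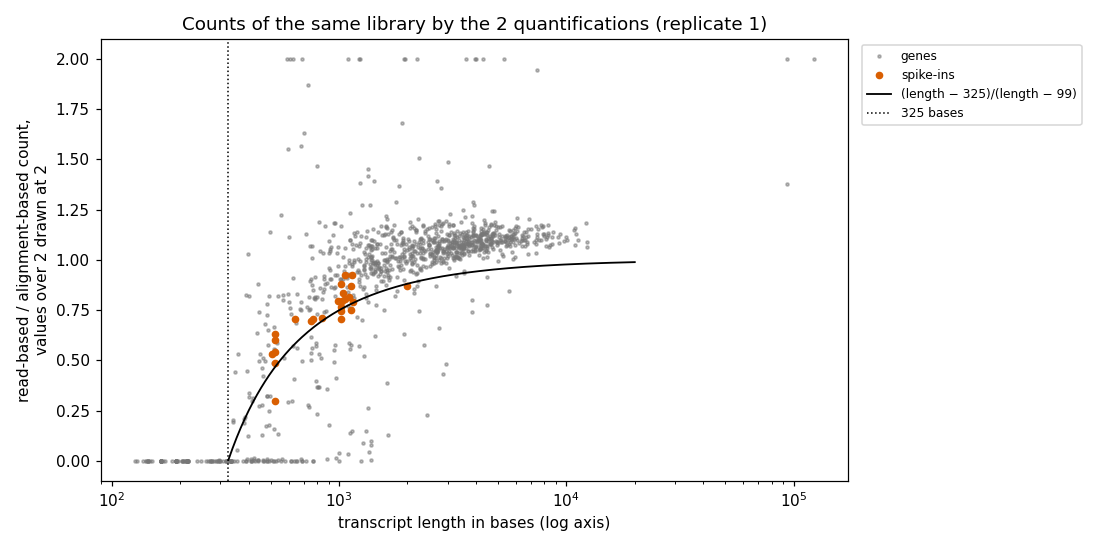
Ratio of read-based estimated counts to alignment-based expected counts in replicate 1 against transcript length in bases on a log axis. Grey points are genes with a single transcript and 200 or more counts, and orange points are ERCC spike-ins. Ratios over 2 are drawn at 2. The line is the length minus 325 bases divided by the length minus 99 bases, the offsets of long transcripts. The dotted line marks 325 bases. The line is not the deposited effective length ratio of short transcripts, which ran from 0.334 to 1.21 for the 75 genes under 325 bases. Genes under 325 bases have a median ratio of 0, and those of 2000 bases or more a median of 1.09.

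Of 37 genes of the steroidogenesis and chromaffin lists at 1 TPM or more, 27 had more than 1 annotated transcript, and 24 of these had the same leading transcript by both methods. In these 27 genes the leading transcript held a median of 89% of a gene's TPM from the means of both libraries, 90% in replicate 1 and 88.2% in replicate 2, and 84.1% by the read-based method. Over all 37 genes, of which 10 had a single transcript and so 100% by construction, the median was 95.3%. Star was divided, with 56.1 ± 0.573% on its leading transcript, as were Ret with 59.9 ± 2.27% and Scg3 with 64 ± 5.01%. The methods disagreed for Hsd3b1, Nr5a1 and Ddc, where the alignment-based leading transcripts held 67.8 ± 2.89%, 80.8 ± 0.495% and 68.7 ± 5.67%. The read-based method gave these same transcripts means of 38.5%, 15.9% and 4.99e-09%. It placed 61.5%, 76.6% and 93% on another transcript of each gene. ERCC spike-ins took 0.904% of expected counts in replicate 1 (95% Clopper-Pearson interval 0.901 to 0.907%) and 0.885% in replicate 2 (0.882 to 0.888%). Relative to the scaling of the genes, summed spike-in counts had a log2 ratio of -0.104 for replicate 2 over replicate 1.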

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

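Alternatives were chosen before the data were examined, except removal of the length trend, read-based counts for list ratios and dispersion, centring of quantifier ratios, a minimum gene length and the restriction to genes with more than 1 transcript, which were chosen after seeing the data. Of the alternatives chosen beforehand 171 kept the result, 16 moved a value, 2 ended a list's standing and 1 created one; of the added ones 58 kept it and 2 moved it. What counted as kept differed by result, so the tally sums unlike checks. Gene counts and the dispersion had to stay within 1.5-fold, and a list ratio had to keep its place among random lists. A list's share of TPM had to stay within the SD of the 2 libraries around their mean. Leaving out either library cannot exceed that SD, so those checks could not fail. DESeq2 or total-count scaling adds 1 constant to every gene's log2 ratio, so list places could hardly change under them. No alternative turned the direction of a list that stood apart. The cause of these differences was not tested, but some follow by construction. A stricter or looser threshold changes the number of genes. Leaving out rows, or their near absence from the read-based tables, raises the TPM shares of the remaining genes. A detection threshold of 10 TPM left 5966 genes. A pseudocount of 0.01 lowered r to 0.9339. DESeq2's median gene-wise estimate lay at its lower bound, a coefficient of variation of 1e-04, with 54.3% of genes at the bound; in simulated data of dispersion 0.01 with no gene changed, 48.3% of genes lay there. Genes over 2-fold apart numbered 243 at a mean of 20 counts and 17 at a mean of 1000. The Schwann and glial median was -0.18 and the immediate early median 0.1 at a mean of 100 counts, and the kidney median was 0.43 with the TPM ratio and 1.22 at a mean of 5 counts. Without mitochondrial, ribosomal RNA and spike-in rows, the steroidogenesis share was 2.28% and the chromaffin share 0.346%; with read-based TPM, the shares were 3.65% and 0.565%, the red cell share 0.387% and the brown adipocyte share 0.293%. Genes over 2-fold apart between quantifiers numbered 8806 at 0.1 TPM, 2935 at 10 TPM and 1290 after centring. The median share of the leading transcript, taken within each quantifier, was 94.2% with read-based TPM, 94.8 to 95.1% with either replicate left out and 89% over genes with more than 1 transcript. Without mitochondrial and ribosomal RNA rows the spike-in share was 1.09%. No paired analysis was possible because the series has 1 group. Depth limits genes of few counts, such as the liver, kidney and division lists, and 2 libraries cannot separate animals from library preparation.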

Other observations

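Of the tests below, only that of the second brown fat list was set before its values were seen; the others were chosen after the results they bear on.

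Within the clock list, whose median did not stand apart, single members differed. Ciart, chosen after its value was seen, stood at 0.55 and 1.46 TPM from 19 and 58 counts, a log2 ratio of 1.6 (95% counting interval 0.85 to 2.45). Per1 stood at 15.9 TPM in replicate 1 and 37.5 TPM in replicate 2, and Per2, also chosen afterwards, at 6.42 and 12.1 TPM, a log2 ratio of 1.03 (95% counting interval 0.94 to 1.13). The output gene Dbp stood at 65.1 and 71.5 TPM, the repressor Nr1d1 at 44.7 and 41.1 TPM, and Arntl, likewise chosen afterwards, at 2.97 and 2.53 TPM. Nr4a1, an immediate early nuclear receptor, stood at 164 and 316 TPM. The class I light chain B2m, a reference gene in the fixed lists, stood at 295 and 458 TPM, and Neat1, chosen afterwards, had a log2 ratio of 1.05.

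Across genes, the ratio of replicate 2 to replicate 1 rose with transcript length, with a Spearman's rho of 0.221 over 12430 genes. The median log2 ratio was -0.075 in the 10% of genes with the shortest transcripts and 0.095 in the 10% with the longest.

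Short RNAs were nearly absent from the read-based tables. Sharing of reads between identical copies is argued against, because 50 short genes with no identical copy had a median count ratio of 0 and a highest ratio of 0.00612. Loss of reads near transcript ends under an assumed fragment length stays open: across 1102 single-transcript genes and spike-ins the count ratio followed the ratio of effective lengths with a Spearman's rho of 0.704, with 0.661 once rows under 325 bases were left out, and across 25 spike-ins with 0.85. The 75 genes under 325 bases had count ratios under 0.05 and a median of 0, while their effective length ratios had a median of 0.428 and ran from 0.334 to 1.21, so the measure is saturated for the short RNAs themselves and their rho of -0.403 decides nothing. No biological explanation applies, since both tables describe the same libraries.

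Brown adipocyte transcripts were lower in the replicate 2 library. The length trend is argued against as the whole cause, since the list median was -0.93 before and -0.88 after its removal. A second list of 17 brown fat genes had a median of -0.56, with 14 of 14 measured members lower, including Cpt1b at 57.8 and 32.5 TPM. This median met the bound set for a larger share of brown adipocytes in replicate 1. The white adipocyte list at -0.51 and the nuclear and mitochondrial respiratory lists at -0.43 and -0.44 met it too. The second list differed from the white one by -0.05 (bootstrap interval over list members -0.33 to 0.15). Such intervals hold no spread between libraries or animals and are too narrow if members vary together. A larger share of brown adipocytes and a larger share of fat of fixed make-up therefore cannot be told apart, and the first brown list's median minus the white one was -0.41 with a bootstrap interval of -0.67 to -0.18. The most abundant members were Ucp1 at 466 TPM, Cox8b at 391 TPM and Kcnk3 at 378 TPM, of which Kcnk3 had a log2 ratio of -0.02, and dissection, animal state and activity of the fat stay open and were not tested.

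Cholesterol supply transcripts were higher in the replicate 2 library. The length trend is argued against, since the list median stayed at 0.23 after its removal. A larger share of cortex is argued against as the whole cause in these libraries, since the list lay 0.22 above the steroidogenesis list (bootstrap interval over list members 0.07 to 0.36). This interval holds no spread between libraries or animals and is too narrow if members vary together. Differences in feeding, time of collection or hormonal state between the samples may contribute but were not tested, and the labels give none of them.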
